A study of Homo sapiens with 28 samples.

How the data were processed

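The series measured DNA supercoiling, protein binding and RNA in RPE1 cells, an hTERT-immortalised human line of retinal pigment epithelium. Supercoiling was reported by biotinylated trimethylpsoralen (bTMP), a compound that intercalates more readily into underwound DNA and is crosslinked to it by ultraviolet light. The crosslinked fragments were pulled down with avidin and hybridised against input DNA on a custom Agilent tiling array. The array carried 173214 non-control probes of 60 bases in 11 tiled regions, called tiles here, which together span 26.2 Mb of chromosomes 1, 3, 11, 16, 17 and X. All coordinates are on hg19 (GRCh37), the build named in the file headers, and are 1-based. There were 28 arrays in 14 groups of 2: 9 bTMP groups, 4 chromatin immunoprecipitation (ChIP) groups and 1 group of total RNA. The labels call the arrays of a group biological replicates, and replicates 1 and 2 carried the dyes in opposite orientation. The arrays lay on 12 slides.

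The deposited scanner files hold a signal intensity per spot and channel, which the authors extracted with Agilent Feature Extraction 10.5.1.1 or 10.7.3.1. The processed intensity in the deposited files was background-subtracted, spatially detrended and dye-normalized by that software, and was not normalized between arrays. The deposited value table of the authors holds log2 ratios of the channels for the bTMP and ChIP arrays, with replicate arrays brought to a similar spread, and log2 signals for the RNA arrays. The steps behind that table are not stated.

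For each bTMP and ChIP array, the log2 ratio of processed signals, pull-down over input, was computed at every non-control probe and centred on the median of the array. A value of 0 is thus the array median, and no absolute level was measured. The direction of 12 arrays is in doubt: the labels and the authors' value table give opposite signs for the bleomycin, naked DNA, ICRF193, camptothecin and both combination groups. As labelled, 34 of the 36 same-dye pairs of arrays between these 12 and the other 6 bTMP arrays correlated negatively across probes, with a median r of -0.278 and a range from -0.606 to 0.0325. The direction of the authors' table was therefore taken for these 12 arrays, as the likelier of the 2 readings and not as a settled one. Values in the labelled direction are given for counts and selected sets beside the affected comparisons, and for the named windows that turned with the other dependence on processing. Differences among untreated, amanitin and recovery arrays do not depend on this choice, but their correlations with naked DNA do.

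The probes were averaged over consecutive 4-kb windows with at least 3 probes (5707 windows) and over 100-kb windows with at least 20 probes (263 windows). The analysis had been planned on windows at transcription start sites, but the gene table at hand (1 row per gene, on GRCh38) is on another build and could not place genes on the array. No gene was placed in a window; genes named as landmarks of a tile are background knowledge. The planned gene sets were replaced by sets of windows, namely the 1903 windows with the most or the least RNA and the 1903 with the highest or lowest GC content. Windows with the most Pol II, topoisomerase I or RNA given GC content, CpG-rich windows (GC at least 50 percent and an observed-to-expected CpG ratio of at least 0.6) and the 11 tiles were added after the data were seen. Sets of long and short genes and named gene lists could not be tested. RNA was the log2 processed signal of the labelled channel minus its 75th percentile over the 37721 probes above background on both RNA arrays. Profiles were drawn around 308 CpG-island-like sites in place of transcription start sites. A site was a run of 500-bp bins, each with at least 2 probes, GC of at least 55 percent and an observed-to-expected CpG ratio of at least 0.6. Its centre value was the mean within 1 kb, and its flank value the mean from 5 to 10 kb away.

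Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over the 18 bTMP arrays with 9 residual degrees of freedom and over the 8 ChIP arrays with 4. Empirical Bayes pooling raised these to 19.2 and 8.51. Windows passed at a Benjamini-Hochberg adjusted p under 0.05, and ChIP was tested against the array median. Rises and falls below are changes of this centred log2 ratio within an array, tested at that threshold by limma. A set's change is the mean over its windows minus the mean over all other windows. Sets were tested with camera, with a preset correlation of 0.01 between windows and again with the correlation estimated, and with fry; the 228 set tests formed 1 family. Neighbouring windows are not independent, and at the estimated correlation no set test passed within this family. Correlations across windows are Spearman's rho with 95 percent intervals from 1000 bootstrap draws of 33 blocks of 1 Mb. The shared SD is the square root of the covariance of the 2 replicates over 100-kb windows. Intervals of shared SDs and of their ratios come from 1000 draws of 1-Mb blocks as well. All these intervals hold the 2 arrays of a group fixed, so they measure variation along the genome and not between arrays. With 2 arrays against 2, the smallest exact permutation p is 0.333, so single values are given with the SD or SE of the replicates and without such a test.

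Windows were named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among windows that passed with non-overlapping replicates. Where fewer than 5 passed in a direction, the rule took the 5 largest with at least 5 probes as not passing; for ChIP it took the 10 most enriched, and for 100-kb windows the 3 largest each way. A few examples from these lists are printed. Windows outside the rule, for comparisons with at most 5 calls, were named after their values were seen.

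The alternatives fixed beforehand were limma's normexp background correction (offset 50), scaling of arrays to a common median absolute deviation, the authors' value table, and only probes well above background in every input channel. Others were a replicate block, the same with a lowess correction for probe GC (span 0.3), slide as a random block, only the groups compared, other window sizes and leaving out each array. The normexp correction used median signals, because 26 of the 28 files hold no mean signal. Arrays in the labelled direction and the value table in its own direction were added after the data were seen. So were RNA classes given GC and a GC correction of the shared SD. The same holds for fits on the inhibitor arrays alone and on the untreated, amanitin and recovery arrays alone. These were run with and without slide as a fixed block.

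The precision is limited by the 2 arrays per group. Between 94.8 and 99.8 percent of the probes were well above background in the input channels, and 160820 probes were so on every bTMP and ChIP array. The 4-kb test was tested on simulated data for amanitin against untreated with 5707 windows. It recovered 17 of 100 windows changed by 0.3 and 86 of 100 changed by 0.6 on the log2 scale. At 100 kb (263 windows) it recovered 8 of 10 and 10 of 10. The ChIP test, simulated for topoisomerase I with 5707 windows, recovered 0 of 100 windows at each size, so enrichment of that size could be missed. Each 4-kb simulation changed only 100 windows of each size, whereas 2558 windows passed for amanitin and 1790 for topoisomerase I in the data. With few changed windows the adjusted threshold is stricter, so these shares do not carry over to comparisons with many changes. Other tools were data.table in version 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.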

Results

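The binding of bTMP, a psoralen that reports DNA supercoiling, was mapped over 11 tiles of the genome of RPE1 cells, with 2 arrays in every group. The bTMP groups were untreated cells, naked DNA, cells given alpha-amanitin for 5 h (an inhibitor of RNA polymerase II), cells left to recover from it for 2 h, and cells nicked with bleomycin for 10 min. Further groups received ICRF193 (an inhibitor of topoisomerase II) or camptothecin (an inhibitor of topoisomerase I) for 5 h, each alone or with amanitin. ChIP arrays measured RNA polymerase II (Pol II) and topoisomerases I, IIα and IIβ in untreated cells, and 2 arrays measured total RNA. The tiles differed widely in composition. The tile at the start of chromosome 11, which holds the imprinted IGF2 and H19 genes, had a mean probe GC content of 60.2 percent, and RNA was detected at 61.0 percent of its probes. The tiles on chromosome 3, around the fragile-site gene FHIT, and on chromosome X from 119 Mb had 38.6 and 38.0 percent GC, with RNA at 13.5 and 15.3 percent of probes. Across 4-kb windows RNA and GC content rose together (rho 0.811), so the contrasts below between RNA-rich and RNA-poor windows are in large part contrasts of GC content. The correlation of replicates across 4-kb windows was 0.854 for untreated, 0.72 for amanitin, 0.863 for recovery and 0.688 for naked DNA. It lay between 0.605 and 0.695 for the other bTMP groups.

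Signed values below follow the direction of the authors' value table, which is likely but not settled for the bleomycin, naked DNA and inhibitor arrays. Naked DNA against untreated cells shows how much of the bTMP pattern comes from sequence alone. In naked DNA bTMP fell steeply with GC content (rho across windows -0.84), from 0.26 ± 0.14 (SD, n = 2) in the lowest GC decile to -0.20 ± 0.09 in the highest. In untreated cells the slope was shallow (rho -0.225, 95 percent interval -0.371 to -0.063), with 0.12 ± 0.05 in the lowest decile and -0.004 ± 0.013 in the highest. Relative to naked DNA, the cells carried more bTMP over RNA-rich sequence, by 0.21 over the 1903 windows with the most RNA and by 0.28 over the chromosome 1 tile, which lies in a neighbourhood of U1 small nuclear RNA genes. Over the X tile from 119 Mb they carried less (-0.14). The largest excess was at chromosome 17, 41436001 to 41440000, in a tile that holds BRCA1 and the U2 small nuclear RNA array, where untreated cells were 1.17 ± 0.10 (SE) above naked DNA (adjusted p = 1.17e-06). The windows on chromosome 1 at 16992001 to 16996000, 16840001 to 16844000 and 17064001 to 17068000 followed with 1.103, 1.047 and 0.927. The lowest window was on chromosome X at 120912001 to 120916000, with -0.84 (adjusted p = 0.0206, 3 probes).

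**Figure D1:**
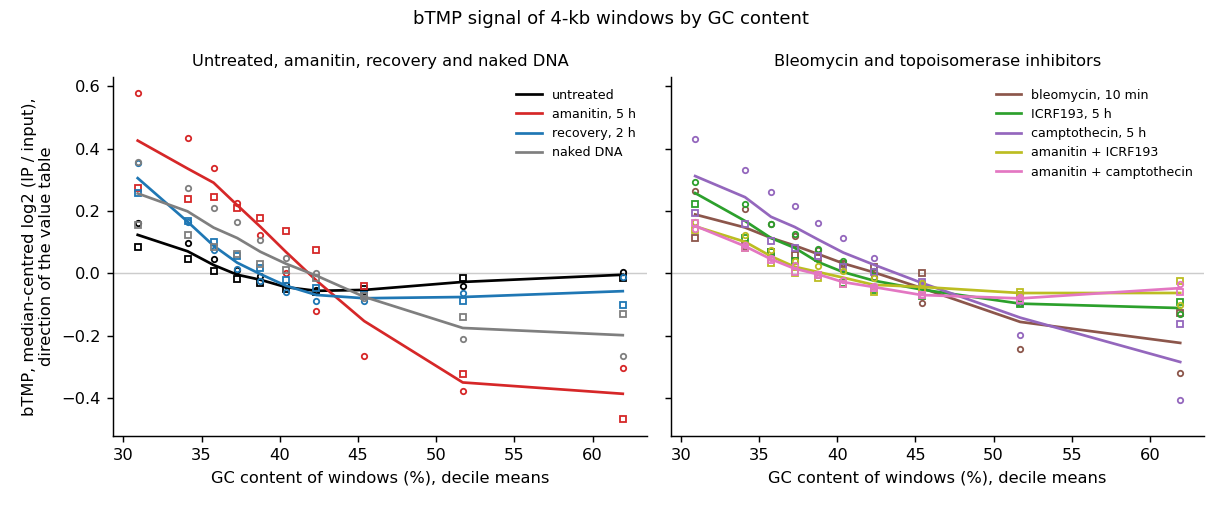
Mean bTMP (median-centred log2 of pull-down over input, direction of the value table) against mean GC content in percent for deciles of 4-kb windows; lines are group means, circles and squares are replicates 1 and 2. In the highest GC decile amanitin lay at -0.39, naked DNA at -0.20 and untreated cells near 0.

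In all, 93 of 5707 windows differed between untreated cells and naked DNA by limma with Benjamini-Hochberg adjustment (64 higher, 29 lower). At 100 kb 85 of 263 did (26 higher, 59 lower): the chromosome 11 start tile had 8 higher and 0 lower, the chromosome 3 tile 0 higher and 21 lower, and the X tile 0 higher and 23 lower. The set changes had adjusted p = 0.0853 (RNA-rich), 0.149 (chromosome 1 tile) and 0.183 (X tile) with an estimated correlation. The excess over naked DNA correlated with RNA across windows with rho 0.558 (0.426 to 0.662), and with 0.253 once GC content was held constant. As labelled, the change was -0.24 for the RNA-rich windows, -0.08 for the chromosome 1 tile and 0.07 for the X tile, so all 3 turned, and 1097 windows passed, whereas the 4 named windows with an excess kept 0.60, 0.74, 0.58 and 0.61. Scaling the arrays alike turned the balance to 448 higher and 710 lower at 4 kb, and naked DNA and untreated arrays lay on different slides; leaving out single arrays gave 7 to 182 windows at 4 kb and, by limma, 0 (80 unadjusted) to 91 at 100 kb.

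Amanitin against untreated cells asks what transcription by Pol II contributes to the pattern. After 5 h of amanitin, bTMP fell over the tiles with the highest GC content and rose over the AT-rich ones. Relative to the other tiles it changed by -0.45 on the chromosome 11 start tile (-0.37 and -0.53 in the replicates), by -0.44 on the chromosome 11 tile at 64 Mb, by -0.42 on chromosome 1 and by -0.36 on chromosome 17. On the X tile from 119 Mb it changed by 0.23 and on the chromosome 3 tile by 0.21. Among the deepest falls, on chromosome 1 the window 16992001 to 16996000 fell by 1.22 ± 0.12 (SE, adjusted p = 2.83e-06), and on chromosome 17 the window 41436001 to 41440000 fell by 1.15 ± 0.10 (adjusted p = 1.51e-06), from 0.88 in untreated cells to -0.27. These windows also led the excess over naked DNA, but the same untreated arrays enter both comparisons, so a chance high value there would appear in both. Further falls were -1.13 and -1.08 on chromosome 1 at 16840001 to 16844000 and 17064001 to 17068000, and -0.93 on chromosome 11 at 1760001 to 1764000. The largest rises lay on chromosome X, with 1.15 ± 0.26 at 120984001 to 120988000 (3 probes) and 1.12 ± 0.13 at 120564001 to 120568000 (18 probes, adjusted p = 3.31e-05). At 100 kb the largest fall was -0.50 ± 0.05 on chromosome 17 at 41400001 to 41500000, and the largest rise 0.54 ± 0.08 on chromosome X at 121400001 to 121500000.

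**Figure D2:**
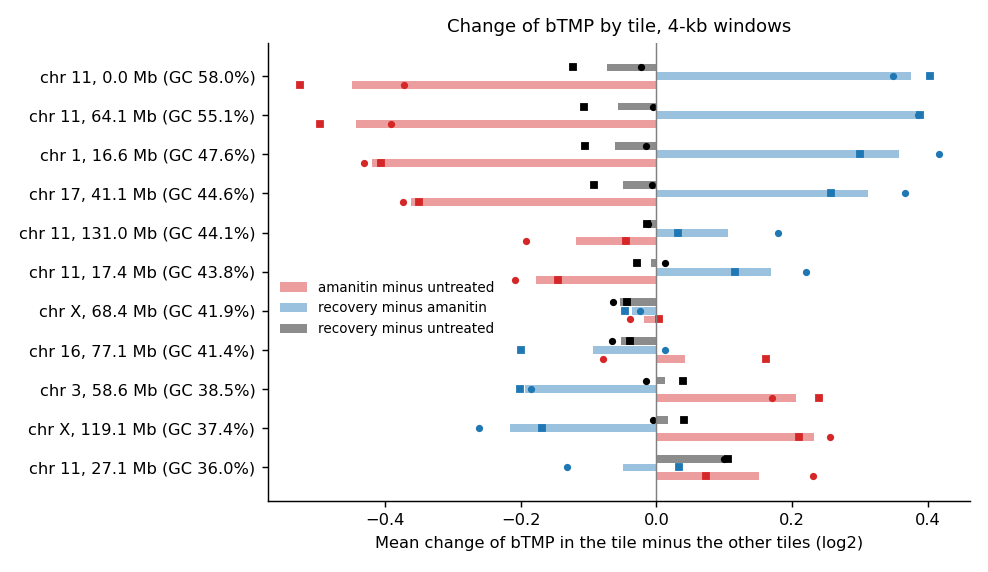
Mean change of bTMP (log2) in each tile minus the other tiles over 4-kb windows, tiles ordered by GC content; bars are group differences and dots are replicates 1 (circles) and 2 (squares). The chromosome 11 start tile changed by -0.45 with amanitin and by 0.38 from amanitin to recovery.

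By limma 2558 of 5707 windows passed (1422 higher, 1136 lower), and 161 of 263 at 100 kb (97 higher, 64 lower). The chromosome 11 start tile had 26 of its 28 100-kb windows lower and 0 higher, the 64-Mb tile all 7 lower, and the chromosome 1 tile all 7 lower. On the chromosome 3 tile 35 of 51 were higher and 1 lower, and on the X tile 28 of 40 were higher and 1 lower. Among the 1903 windows with the most RNA 1027 fell and 77 rose, and the set changed by -0.41 (adjusted p = 0.0626 with an estimated correlation). Among the 1903 with the highest GC content 1063 fell and 28 rose, with a change of -0.45 (adjusted p = 0.0626 with an estimated correlation). Windows with more RNA than their GC content predicts changed by -0.10 (adjusted p = 0.218 with an estimated correlation). The rho of bTMP with GC content was -0.844 after amanitin, and the correlation with naked DNA across windows was 0.821, against 0.261 for untreated cells; both correlations with naked DNA change sign in the labelled direction. The shared SD over 100-kb windows was 0.253 after amanitin and 0.126 in untreated cells, a ratio of 2.01 (1.48 to 2.73). After removal of each array's GC trend that ratio was 0.98 (0.752 to 1.31), and the shared SD of the change itself went from 0.248 to 0.136. With a replicate block added, 1077 windows passed (385 higher, 692 lower), against 2800 with the block alone. Of the 1077, 891 also passed in the same direction in the fit with neither the block nor the GC correction. Leaving out single arrays gave 965 to 2229 windows at 4 kb and 135 to 185 at 100 kb, fewest without an untreated array.

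The recovery arrays ask whether the change was undone once amanitin was removed. After 2 h, bTMP rose again on the tiles where it had fallen, by 0.38 on the chromosome 11 start tile, 0.39 at 64 Mb, 0.36 on chromosome 1 and 0.31 on chromosome 17 relative to the other tiles. It fell on the X tile from 119 Mb (-0.21) and on chromosome 3 (-0.19). The largest single rise was 0.87 ± 0.17 (SE) on chromosome 11 at 516001 to 520000, followed by 0.83 and 0.72 on chromosome 1 at 16856001 to 16860000 and 17096001 to 17100000. The largest falls were -0.89, -0.87 and -0.82 on chromosome X at 121724001 to 121728000, 120564001 to 120568000 and 69108001 to 69112000. At 100 kb the chromosome 17 window 41400001 to 41500000 regained 0.40 ± 0.05. By limma 1866 windows differed between recovery and amanitin (905 higher, 961 lower), and 147 at 100 kb (62 higher, 85 lower). On the chromosome 11 start tile 388 of 618 windows rose and 2 fell, and on the X tile 4 of 754 rose and 257 fell. The set changes had adjusted p = 0.174 and 0.159 with an estimated correlation. The amanitin arrays enter both comparisons, so that chance deviations of these arrays would also appear as a fall and a return. Fitted with its own 4 arrays alone the 4-kb comparison called 0 windows by limma (2091 at an unadjusted p under 0.05) and the 100-kb comparison 123, and without recovery replicate 1 the 4-kb count was 14.

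Recovery was also compared with untreated cells, in the fit of all 18 bTMP arrays. Across windows their bTMP correlated with rho 0.872. Recovery stayed lower than untreated in 5 windows, and higher in 0 by limma, with 150 windows at an unadjusted p under 0.05. On chromosome 11 the window 1760001 to 1764000 differed by -0.70 ± 0.13 (SE, adjusted p = 0.0236). On chromosome 17 the windows 41436001 to 41440000 and 41444001 to 41448000 differed by -0.69 ± 0.10 (adjusted p = 0.00528) and -0.57 ± 0.09 (adjusted p = 0.00851). On chromosome 1 the windows 16992001 to 16996000 and 16840001 to 16844000 differed by -0.65 and -0.60 (both adjusted p = 0.0236). At 100 kb limma called 0 windows, with 9 at an unadjusted p under 0.05. The chromosome 11 tile from 27 Mb, which holds BDNF, was higher by 0.10 than the other tiles in each replicate (adjusted p = 0.171 with an estimated correlation), and the RNA-rich windows differed by -0.09 (adjusted p = 0.149 with an estimated correlation). The shared SD was 1.33 times that of untreated cells (1.21 to 1.41 over blocks of the genome, with the arrays held fixed). With normexp correction 2 windows passed, and 1 passed with the value table. On the untreated, amanitin and recovery arrays alone limma called 0 windows without a block (160 at an unadjusted p under 0.05). With slide as a fixed block on these arrays it called 7 (1 higher, 6 lower). Leaving out single arrays gave 0 to 3 windows by limma (52 to 152 unadjusted), and with only the 4 arrays compared in the fit 26 windows passed at 4 kb (15 higher, 11 lower) and 32 at 100 kb (32 higher, 0 lower).

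Bleomycin, which nicks DNA and so releases torsion, was compared with untreated cells. The bleomycin and untreated arrays lay on different slides, so drug and slide cannot be told apart here. The RNA-rich windows lay at -0.17 relative to the rest (adjusted p = 0.0794 with an estimated correlation), and bTMP followed GC content with rho -0.759. A single window passed, on chromosome 11 at 2668001 to 2672000, where bTMP was higher by 0.93 ± 0.14 (SE, adjusted p = 0.00912); it holds 3 probes and was named after its value was seen. By limma 1 window passed at 4 kb (751 at an unadjusted p under 0.05) and 0 at 100 kb (89 unadjusted). As labelled the RNA-rich windows lay at 0.21, that window at -0.08, and 1161 windows passed; scaling the arrays alike gave 571. At 100 kb the replicate block gave 37 windows (16 higher, 21 lower), 14 with removal of the GC trend added, and scaling gave 149.

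Inhibition of topoisomerases asks which enzyme removes the supercoils. The camptothecin and untreated arrays lay on different slides and were extracted with different versions of the software. Drug, slide and version thus cannot be told apart here. With camptothecin, in the direction of the value table only, bTMP fell over the chromosome 11 start tile and rose over the chromosome 3 and X tiles. On the first, 23 of 28 windows of 100 kb were lower and 0 higher. On chromosome 3 and X, 17 of 51 and 14 of 40 were higher and 0 lower. In that direction the named falls at 100 kb were -0.32, on chromosome 11 at 800001 to 900000, 1400001 to 1500000 and 500001 to 600000. The largest rise was 0.28 on chromosome X at 121300001 to 121400000 (all adjusted p = 0.0247 by limma). At 4 kb the largest rise was 1.02 on chromosome 11 at 27556001 to 27560000 (adjusted p = 0.0405), and the largest fall was -0.72 at 516001 to 520000 (adjusted p = 0.037). The RNA-rich windows changed by -0.23 (12 higher, 61 lower; adjusted p = 0.0794 with an estimated correlation), and the 51 CpG-rich windows by -0.43 (0 higher, 19 lower; adjusted p = 0.126 with an estimated correlation). In all 185 windows passed by limma (121 higher, 64 lower), and 62 at 100 kb (35 higher, 27 lower). In the labelled direction, 3 of the 185 passed with the same sign and 50 with the opposite sign. As labelled 1842 windows passed, the RNA-rich windows lay at 0.26, the CpG-rich at 0.13 and the chromosome 11 start tile at 0.31; by limma normexp correction left 15 at 4 kb and 0 at 100 kb (89 unadjusted). Removal of the GC trend with the replicate block left 0 at 4 kb by limma (777 unadjusted) and 1 at 100 kb, and leaving out single arrays gave 0 to 947 and 0 to 127 windows.

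With ICRF193, compared under the same limit of slide and extraction version, few windows changed. bTMP rose on chromosome X at 122268001 to 122272000 by 0.94 ± 0.19 (SE, adjusted p = 0.0443, 3 probes) and fell on chromosome 11 at 516001 to 520000 by 0.88 ± 0.17 (adjusted p = 0.0377). The RNA-rich windows lay at -0.12 relative to the rest (adjusted p = 0.175 with an estimated correlation). By limma 13 windows passed at 4 kb (11 higher, 2 lower) and 0 at 100 kb, with 23 at an unadjusted p under 0.05. As labelled 1423 windows passed and the RNA-rich windows lay at 0.15; scaling gave 75 higher and 35 lower, and normexp correction 0 windows.

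Between the inhibitors 2 windows differed, both lower with ICRF193 than with camptothecin, on chromosome 11 at 31512001 to 31516000 (-0.79, 4 probes) and 30316001 to 30320000 (-0.72, 3 probes), each with adjusted p = 0.0293 by limma. They were named after their values were seen. The RNA-rich windows lay 0.11 higher with ICRF193. At 100 kb limma called 0 windows (17 at an unadjusted p under 0.05). This comparison only changes sign in the labelled direction, and the 4 inhibitor groups shared slides; on the inhibitor arrays alone limma called 0 windows without a block (457 unadjusted) and 1 with slide as a fixed block, and on all arrays 5 with slide as a random block.

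Adding amanitin to an inhibitor tests whether loss of transcription acts when topoisomerases are blocked. In the presence of ICRF193, bTMP fell in 2 windows of the chromosome 17 tile, by 0.68 at 41436001 to 41440000 (adjusted p = 0.00633) and by 0.57 at 41152001 to 41156000 (adjusted p = 0.0326). These windows too were named after their values were seen. In the presence of camptothecin limma called 0 windows, with 1028 at an unadjusted p under 0.05. At 100 kb limma called 0 for either inhibitor (2 and 64 at an unadjusted p under 0.05). For camptothecin these counts moved to 17 at 4 kb and 1 at 100 kb with a replicate block, and to 25 and 40 with slide as a random block. The GC-rich windows, which amanitin alone lowered, lay higher by 0.08 when it was added to ICRF193 (adjusted p = 0.337 with an estimated correlation) and by 0.20 when it was added to camptothecin (adjusted p = 0.0853 with an estimated correlation). Both values turn sign in the labelled direction, in which the chromosome 17 windows lay at 0.68 and 0.57; fitted on the 8 inhibitor arrays alone they kept -0.68 ± 0.10 and -0.57 ± 0.11 (SE), but limma called 0 windows for ICRF193 without a block (400 unadjusted) and 0 with slide as a fixed block (563 unadjusted). The amanitin effect itself differed with and without ICRF193 in 1745 windows (715 higher, 1030 lower) and with and without camptothecin in 2388 (935 higher, 1453 lower). As labelled these were 119 and 211 windows. The arms with and without inhibitor lay on different slides and were extracted with different versions of the software.

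Around 308 CpG-island-like sites, which often mark promoters, untreated cells had a local peak of bTMP. The centre exceeded the flanks by 0.099 ± 0.057 (SD, n = 2), against -0.017 ± 0.064 in naked DNA, 0.004 ± 0.066 after amanitin and 0.079 ± 0.049 after recovery. At the sites with the least RNA the centre lay 0.087 ± 0.018 above the flanks in untreated cells, whereas it lay at -0.136 ± 0.062 after amanitin and at -0.127 ± 0.078 in naked DNA. At the sites with the most RNA the peak was 0.116 ± 0.095 in untreated cells, 0.132 ± 0.057 after amanitin and 0.086 ± 0.047 in naked DNA, so there it was not particular to cells in the direction of the value table. GC content was 53.9 percent at the centre and 44.8 percent in the flanks of the least-RNA sites. At the most-RNA sites it was 65.4 and 58.9 percent. The low centres at least-RNA sites after amanitin and in naked DNA thus cannot be told apart from the steep fall of bTMP with GC content in these groups. With camptothecin the centre lay at -0.110 ± 0.074 over all sites, and at 0.11 as labelled. The naked DNA values at these sites also change sign as labelled, so that the least-RNA sites would then peak in naked DNA as they do in untreated cells. Of the 103 sites with the most RNA 76 lay on the chromosome 11 start tile.

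**Figure D3:**
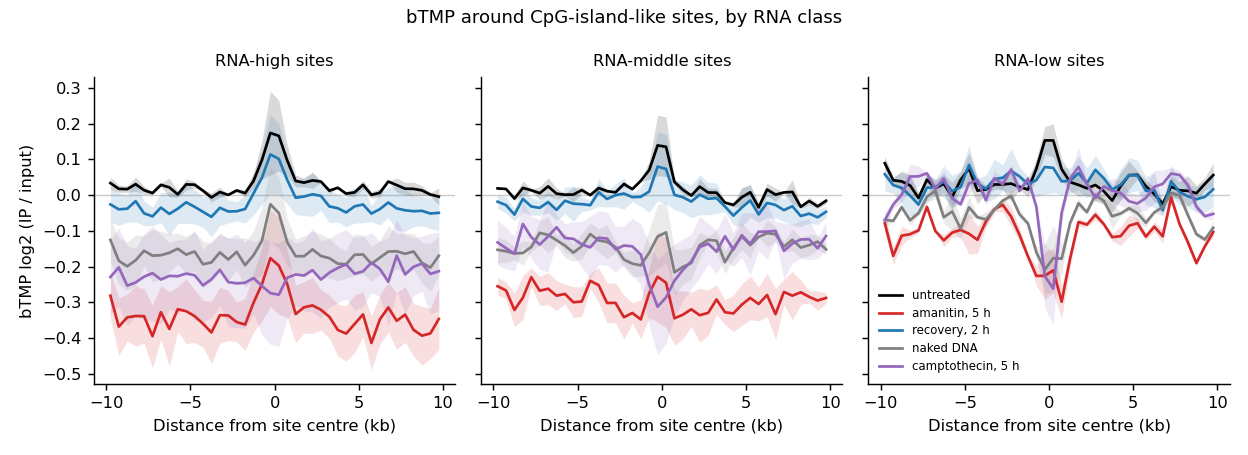
bTMP (log2 of pull-down over input) against distance in kb from the centre of CpG-island-like sites, for the sites with the most, intermediate and the least RNA; lines are means of 2 arrays and bands span the replicates. Over all sites the centre exceeded the flanks by 0.099 in untreated cells and by 0.004 after amanitin.

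The ChIP arrays show where the polymerase and the topoisomerases bound. Topoisomerase I followed GC content: its mean over the 1903 windows with the highest GC content was 0.40, against -0.22 over those with the lowest, and it was 0.48 on the chromosome 11 start tile. Its 3 highest windows, with 3 probes each, were on chromosome 3 at 63012001 to 63016000 (2.80 ± 0.39 SE) and on chromosome X at 119320001 to 119324000 (2.17) and 119260001 to 119264000 (1.92). A better covered window reached 1.27 ± 0.13 on chromosome 11 at 64380001 to 64384000 (27 probes, adjusted p = 0.00133). Pol II followed topoisomerase I across windows with rho 0.844 (0.764 given GC content), and its most enriched window, on chromosome 17 at 41624001 to 41628000, measured 0.84 ± 0.16 (adjusted p = 0.233, not passing) where topoisomerase I measured 1.52 ± 0.16. Topoisomerase IIβ was highest on chromosome X at 68940001 to 68944000 (0.71, adjusted p = 0.0331). By limma topoisomerase I passed in 1790 windows (1275 above and 515 below the array median), topoisomerase IIβ in 549 (16 above, 533 below) and Pol II in 0 (795 at an unadjusted p under 0.05). With the value table these were 314 for topoisomerase I (159 above, 155 below) and 180 for IIβ (130 above, 50 below), a turned balance. Window means of IIβ lay below the array median in every GC decile but the highest, from -0.273 in the lowest to 0.003 in the highest. Its calls below the median thus do not by themselves show depletion of the enzyme. Scaling the arrays alike left 0 for topoisomerase I by limma (1271 unadjusted) but gave 445 for Pol II (387 above, 58 below), and normexp correction gave 13 for Pol II and left 30 for IIβ. Topoisomerase IIα passed in 1 window, below the median, on chromosome X at 121152001 to 121156000 (-1.16 ± 0.11, adjusted p = 0.014), named after its value was seen. Replicates correlated with r 0.918 for topoisomerase I and 0.672 for Pol II, but with 0.102 and 0.141 for IIα and IIβ, so single windows of the type II enzymes are poorly determined. The excess of bTMP in untreated cells over naked DNA correlated with Pol II with rho 0.347 and with topoisomerase I with 0.374; given GC content these were 0.071 and 0.016, and as labelled -0.354 and -0.487.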

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

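Every use of a test for or against an explanation in this part was chosen after the results were seen. Some of the counts come from alternatives fixed beforehand. The amanitin effect differed with and without ICRF193 in 1745 windows and with and without camptothecin in 2388 (119 and 211 in the labelled direction), each by a test of the difference itself. A signal also appeared in data outside the comparisons: 28.28 and 22.19 percent of probes on RNA arrays 1 and 2 were well above background in the channel for which the labels give no sample. That channel correlated with the labelled channel across probes with r 0.953 and 0.955.

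Amanitin lowered bTMP over the GC-rich tiles and raised it over AT-rich ones. A GC bias of the amanitin arrays as the whole cause is argued against by 1077 windows (385 higher, 692 lower) that still passed after removal of each array's GC trend with the replicate block, and a wider scale of those arrays by 1745 that passed with arrays scaled alike. The correction lowered the shared SD of the change over 100-kb windows from 0.248 to 0.136, and with the replicate block 153 of 263 windows passed after the correction and 175 without it, 125 of them in both with the same direction; how much of the removed part is bias was not separated. A loss of the cellular pattern that leaves the sequence preference of bTMP may contribute. Amanitin correlated with naked DNA more strongly than untreated cells did, by 0.56 in rho (0.402 to 0.701). That hypothesis rests on the direction of the naked DNA arrays, and unequal amounts of bTMP or crosslinking between arrays were not tested. The shared SD after amanitin was 1.93 times that of naked DNA (1.8 to 2.04). This ratio measures amplitude on arrays of different slides, so it cannot decide whether the pattern of naked DNA returned in full.

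For 12 arrays the labels and the value table give opposite directions. Psoralens crosslink preferentially at TA steps, yet naked DNA as labelled fell with the number of TA steps per probe (rho -0.814), which argues against a real opposite pattern in naked DNA. That relation was mostly shared with GC content, since in the direction of the value table the rho with TA steps given GC was 0.108 (0.067 to 0.147), so the argument is a weak one. The same value, -0.814, is what exchanged channel labels would give, so these are a candidate source. For the treated cells the highest rho with TA steps as labelled was -0.395, but without an array of settled direction in these groups a real opposite pattern and an exchange cannot be told apart.

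Over GC-rich windows amanitin alone changed bTMP by -0.446 relative to the rest. In the direction of the value table, amanitin added to ICRF193 changed it by 0.079 ± 0.017 (SD). Added to camptothecin it changed it by 0.199 ± 0.177, so both changes were opposite in sign to amanitin alone. As labelled they were -0.079 and -0.199, of the same sign. Whether the effect turned thus depends on the unsettled direction. In either direction the amanitin effect over these windows was smaller in size in the presence of a topoisomerase inhibitor. The direction of the inhibitor arrays is argued against as the whole cause over GC-rich windows, where in the labelled direction the difference was still 0.367 with ICRF193 and 0.247 with camptothecin, above 0 in both replicates; with camptothecin it was only 0.187 ± 0.307 (SD) on the chromosome 11 start tile and 0.097 ± 0.25 over CpG-rich windows, each below 0 in replicate 1. With arrays scaled alike, 1149 (ICRF193) and 1546 (camptothecin) windows passed. That scaling used the median absolute deviation across probes. It was 0.252 to 0.522 on the inhibitor arrays and 0.256 and 0.218 on untreated ones. For equal replicate numbers the inhibitor arrays were thus not the narrower ones in this measure. It includes the noise of single probes, so the scaling cannot decide whether the pattern itself was compressed on the inhibitor arrays. The shared SD of ICRF193 alone was 0.991 times that of untreated cells, but that of amanitin with camptothecin was 0.575 times that of camptothecin (0.45 to 0.719). After removal of the GC trend these ratios were 0.733 (0.671 to 0.779) and 1.06 (0.956 to 1.16). That of camptothecin to untreated cells went from 1.24 to 0.604 (0.561 to 0.659). Apart from the probe GC trend, the pattern was thus narrower with either inhibitor alone than in untreated cells. The same held for bleomycin (0.564, 0.474 to 0.664) and for naked DNA (0.616, 0.504 to 0.795), which also lay on other slides than untreated cells. The narrowing was therefore not particular to the inhibitors, and drug and slide cannot be told apart in it. With the replicate block, removal of the probe GC trend took the count for ICRF193 from 2084 to 700. The 700 argue against a bias by probe GC as the whole cause, but a bias over longer stretches was not tested. For camptothecin the count went from 2684 to 123, so that GC bias and a real difference that follows GC content cannot be told apart there. Nor can a separate batch of cells and slides be told apart from the inhibitors, since no slide held both arms (2315 windows passed with slide as a random block), and a dependence of the amanitin effect on topoisomerase activity stays open as an untested biological explanation.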

How the results depend on the processing

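The choices in this part were fixed before the data were examined except 4, chosen after the results were seen. These were the labelled direction of arrays, the value table in its own direction, RNA classes given GC content and the GC correction of the shared SD. The fits on subsets of arrays with and without slide as a fixed block, given above, were also chosen after the data were seen. Counts are windows past an adjusted p of 0.05 in limma; an unadjusted count at p under 0.05 stands beside each 0. Where a value changed, the cause was not tested. The amanitin comparison passed in 965 (without untreated replicate 2) to 2933 (slide as a random block) of the 4-kb windows and in 135 to 188 of the 100-kb windows, and its named windows kept their direction under every setting run on them. Among the values of named windows under alternatives, 249 kept direction and call, 37 kept the direction and lost the call, and 20 turned. Those that turned were 10 with the arrays as labelled and 10 with the value table turned to the labels. Of the tests of the RNA-rich set, or of a set put in its place, 57 kept both, 8 lost the call and 7 turned. Their calls were taken at the preset correlation. With the correlation estimated, 9 kept both and 3 lost the call. These counts do not show that a set passed in the family of all set tests at the estimated correlation, where none did. Among the other values 202 stayed within the limits of change, 149 moved, 2 lost support and 14 turned. The 4 recovery windows other than the one on chromosome 17 from 41436001 lost their call with the value table, as 3 of them did with normexp correction. The amanitin rise on chromosome X from 121388001 had an adjusted p = 0.0526 with GC correction.

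With a replicate block, which treats equally numbered arrays as a pair, the counts at 4 kb were 189 for untreated against naked DNA, 48 for ICRF193, 431 for camptothecin, 5 for ICRF193 against camptothecin and 17 for amanitin added to camptothecin. At 100 kb 37 passed for bleomycin, 102 for camptothecin and 1 for amanitin added to camptothecin. With the replicate block and removal of the probe GC trend the counts at 4 kb were 173 for untreated against naked DNA, 1077 for amanitin, 1056 for recovery against amanitin, 2 for bleomycin, 0 (705 unadjusted) for ICRF193 and 0 (777 unadjusted) for camptothecin. Also at 4 kb 1 passed for ICRF193 against camptothecin, 700 for the difference in amanitin effect with ICRF193 and 123 for the difference in amanitin effect with camptothecin. At 100 kb 14 passed for bleomycin and 1 for camptothecin. ChIP counts were 708 for topoisomerase I, 0 (1010 unadjusted) for topoisomerase IIα and 358 for topoisomerase IIβ. With slide as a random block the counts at 4 kb were 5 for ICRF193, 5 for ICRF193 against camptothecin, 4 for amanitin added to ICRF193 and 25 for amanitin added to camptothecin. At 100 kb 40 passed for amanitin added to camptothecin. With only the arrays compared in the fit, which leaves fewer residual degrees of freedom, the counts at 4 kb were 304 for untreated against naked DNA, 0 (2091 unadjusted) for recovery against amanitin, 26 for recovery against untreated, 2 for bleomycin, 0 (1066 unadjusted) for ICRF193 and 0 (1594 unadjusted) for camptothecin. Also at 4 kb 4 passed for ICRF193 against camptothecin and 0 (435 unadjusted) for amanitin added to ICRF193. At 100 kb 139 passed for untreated against naked DNA, 32 for recovery against untreated, 28 for ICRF193, 1 for amanitin added to ICRF193 and 17 for amanitin added to camptothecin. ChIP counts were 1047 for Pol II, 3314 for topoisomerase I, 0 (419 unadjusted) for topoisomerase IIα and 0 (663 unadjusted) for topoisomerase IIβ. After normexp background correction the counts at 4 kb were 56 for untreated against naked DNA, 2 for recovery against untreated, 0 (515 unadjusted) for ICRF193, 15 for camptothecin and 0 (246 unadjusted) for ICRF193 against camptothecin. At 100 kb 42 passed for untreated against naked DNA and 0 (89 unadjusted) for camptothecin. ChIP counts were 13 for Pol II, 0 (669 unadjusted) for topoisomerase IIα and 30 for topoisomerase IIβ. With arrays scaled to a common median absolute deviation the counts at 4 kb were 1158 for untreated against naked DNA, 979 for recovery against amanitin, 22 for recovery against untreated, 571 for bleomycin, 110 for ICRF193 and 569 for camptothecin. Also at 4 kb 0 (343 unadjusted) passed for ICRF193 against camptothecin, 0 (539 unadjusted) for amanitin added to ICRF193, 1149 for the difference in amanitin effect with ICRF193 and 1546 for the difference in amanitin effect with camptothecin. At 100 kb 164 passed for untreated against naked DNA, 8 for recovery against untreated, 149 for bleomycin, 36 for ICRF193 and 129 for camptothecin. ChIP counts were 445 for Pol II, 0 (1271 unadjusted) for topoisomerase I, 37 for topoisomerase IIα and 301 for topoisomerase IIβ. With bright probes only the counts at 4 kb were 2 for amanitin added to camptothecin. ChIP counts were 3 for topoisomerase IIα. With the authors' value table turned to the labels the counts at 4 kb were 1173 for untreated against naked DNA, 1 for recovery against untreated, 1216 for bleomycin, 1461 for ICRF193, 1873 for camptothecin and 0 (572 unadjusted) for ICRF193 against camptothecin. Also at 4 kb 0 (427 unadjusted) passed for amanitin added to ICRF193, 270 for the difference in amanitin effect with ICRF193 and 264 for the difference in amanitin effect with camptothecin. At 100 kb 138 passed for untreated against naked DNA, 125 for bleomycin, 122 for ICRF193, 141 for camptothecin and 31 for amanitin added to camptothecin. ChIP counts were 314 for topoisomerase I, 105 for topoisomerase IIα and 180 for topoisomerase IIβ. With that table in its own direction the counts at 4 kb were 1 for recovery against untreated, 0 (720 unadjusted) for ICRF193, 478 for camptothecin, 0 (572 unadjusted) for ICRF193 against camptothecin and 0 (427 unadjusted) for amanitin added to ICRF193. At 100 kb 56 passed for bleomycin and 31 for amanitin added to camptothecin. In 2-kb windows the counts were 88 for camptothecin and 0 (969 unadjusted) for ICRF193 against camptothecin. ChIP counts were 2908 for topoisomerase I and 0 (1472 unadjusted) for topoisomerase IIα. In 10-kb windows the counts were 1323 for amanitin, 1079 for recovery against amanitin, 2 for recovery against untreated, 0 (427 unadjusted) for bleomycin, 4 for ICRF193 and 88 for camptothecin. In these larger windows 0 (206 unadjusted) passed for ICRF193 against camptothecin, 1 for amanitin added to ICRF193, 1 for amanitin added to camptothecin, 1105 for the difference in amanitin effect with ICRF193 and 1323 for the difference in amanitin effect with camptothecin. ChIP counts were 1 for Pol II, 900 for topoisomerase I and 0 (403 unadjusted) for topoisomerase IIα. In 50-kb windows, set against 100-kb windows, the counts were 147 for untreated against naked DNA, 327 for amanitin, 291 for recovery against amanitin, 1 for recovery against untreated and 99 for camptothecin. In 200-kb windows the counts were 46 for untreated against naked DNA, 84 for amanitin, 81 for recovery against amanitin and 36 for camptothecin.

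With the arrays as labelled the counts at 4 kb were 1097 for untreated against naked DNA, 1161 for bleomycin, 1423 for ICRF193, 1842 for camptothecin, 2 for ICRF193 against camptothecin and 2 for amanitin added to ICRF193. Also at 4 kb 119 passed for the difference in amanitin effect with ICRF193 and 211 for the difference in amanitin effect with camptothecin. At 100 kb 119 passed for bleomycin, 97 for ICRF193 and 133 for camptothecin. For the named windows that follow, the value in brackets comes from the authors' value table likewise turned to the labels. In its own direction that table kept the sign of the named windows, 24 with the same call and 10 without it. Named windows turned to 0.296 (0.315 with the value table) for untreated against naked DNA on chromosome X from 120912001, -1.044 (-0.986 with the value table) for ICRF193 on chromosome X from 122268001, 0.288 (0.297 with the value table) for ICRF193 on chromosome 11 from 516001, -0.544 (-0.509 with the value table) for camptothecin on chromosome 11 from 27556001 and 0.13 (0.132 with the value table) for camptothecin from 516001. Others turned to -0.075 (-0.107 with the value table) for bleomycin from 2668001, 0.723 (0.653 with the value table) for ICRF193 against camptothecin from 30316001, 0.787 (0.66 with the value table) for the same comparison from 31512001, 0.676 (0.664 with the value table) for amanitin added to ICRF193 on chromosome 17 from 41436001 and 0.574 (0.591 with the value table) for the same from 41152001. The RNA-rich windows then turned to -0.243 for untreated against naked DNA, 0.212 for bleomycin, 0.153 for ICRF193, 0.263 for camptothecin, -0.109 for ICRF193 against camptothecin, -0.064 for amanitin added to ICRF193 and -0.177 for amanitin added to camptothecin. The rho of untreated minus naked DNA turned to -0.524 with RNA, -0.711 with GC content, -0.354 with Pol II, -0.487 with topoisomerase I, 0.075 with topoisomerase IIα and -0.148 with topoisomerase IIβ. The centre of CpG-island-like sites minus their flanks turned to 0.017 for naked DNA, -0.019 for ICRF193, 0.11 for camptothecin, -0.072 for amanitin with ICRF193 and -0.07 for amanitin with camptothecin. Given GC content that rho was 0.071 with Pol II and 0.016 with topoisomerase I, with intervals that include 0, and it turned to -0.08 with topoisomerase IIβ. With topoisomerase IIα it turned to 0.001 with the value table. The shared SD over 100-kb windows moved after the GC correction to 0.0727 for Pol II, 0.168 for topoisomerase I, 0.0494 for topoisomerase IIα, 0.0694 for bleomycin, 0.0759 for naked DNA, 0.121 for amanitin, 0.0903 for ICRF193 and 0.0744 for camptothecin. The shared SD over 100-kb windows moved after normexp correction to 0.0533 for topoisomerase IIα, 0.0117 for topoisomerase IIβ and 0.0874 for bleomycin. The shared SD over 100-kb windows moved with the value table to 0.173 for topoisomerase I, 0.113 for topoisomerase IIα and 0.108 for topoisomerase IIβ.

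With each array left out in turn, the lone array left in its group was assumed to vary like the other groups; each pair of counts is without replicate 1 and without replicate 2 of the group named. Untreated against naked DNA at 4 kb gave 10 and 182 for naked DNA and 7 and 10 for untreated. Amanitin at 4 kb gave 1210 and 965 for untreated and 2229 and 2058 for amanitin. Recovery against amanitin at 4 kb gave 2033 and 884 for amanitin and 14 and 999 for recovery. Recovery against untreated at 4 kb gave 0 and 0 for untreated and 3 and 0 for recovery. Bleomycin at 4 kb gave 0 and 0 for bleomycin and 0 and 0 for untreated. ICRF193 at 4 kb gave 0 and 0 for untreated and 0 and 12 for ICRF193. Camptothecin at 4 kb gave 5 and 0 for untreated and 0 and 947 for camptothecin. ICRF193 against camptothecin at 4 kb gave 0 and 1 for ICRF193 and 0 and 8 for camptothecin. Amanitin added to ICRF193 at 4 kb gave 0 and 3 for ICRF193 and 0 and 2 for amanitin with ICRF193. Amanitin added to camptothecin at 4 kb gave 0 and 400 for camptothecin and 0 and 0 for amanitin with camptothecin. The difference in amanitin effect with ICRF193 at 4 kb gave 772 and 572 for untreated, 1805 and 1580 for amanitin, 669 and 1402 for ICRF193 and 1002 and 987 for amanitin with ICRF193. The difference in amanitin effect with camptothecin at 4 kb gave 1826 and 1483 for untreated, 2266 and 2543 for amanitin, 1275 and 2723 for camptothecin and 1897 and 1730 for amanitin with camptothecin. Untreated against naked DNA at 100 kb gave 3 and 91 for naked DNA and 0 and 4 for untreated. Amanitin at 100 kb gave 140 and 135 for untreated and 164 and 185 for amanitin. Recovery against amanitin at 100 kb gave 164 and 150 for amanitin and 105 and 136 for recovery. Recovery against untreated at 100 kb stayed at 0 with any array left out (0 to 8 unadjusted). Bleomycin at 100 kb gave 0 and 49 for bleomycin and 0 and 0 for untreated. ICRF193 at 100 kb stayed at 0 with any array left out (1 to 28 unadjusted). Camptothecin at 100 kb gave 0 and 0 for untreated and 0 and 127 for camptothecin. ICRF193 against camptothecin at 100 kb gave 0 and 0 for ICRF193 and 0 and 10 for camptothecin. Amanitin added to ICRF193 at 100 kb stayed at 0 with any array left out (1 to 9 unadjusted). Amanitin added to camptothecin at 100 kb gave 0 and 89 for camptothecin and 0 and 0 for amanitin with camptothecin. Pol II ChIP gave 0 and 0 for Pol II. Topoisomerase I ChIP gave 863 and 250 for topoisomerase I. Topoisomerase IIα ChIP gave 0 and 0 for topoisomerase IIα. Topoisomerase IIβ ChIP gave 395 and 1192 for topoisomerase IIβ. Beside these counts of 0, 52 to 901 windows at 4 kb, 0 to 80 windows at 100 kb and 90 to 1105 windows for ChIP had an unadjusted p under 0.05.

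Depth on these arrays is signal over background. With 84.0 to 99.8 percent of pull-down probes and 94.8 to 99.8 percent of input probes well above it, restriction to probes bright in every input channel moved 2 counts beyond 1.5 times, those given above.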

Other observations

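The first test of the recovery windows in this part was fixed before its result was seen; its repeats without called windows and the comparisons across groups, RNA and ChIP in the first paragraphs were chosen after the values were seen. A few sharp peaks stood out on chromosomes 1 and 17. At chromosome 17, 41436001 to 41440000, bTMP measured 0.88 ± 0.05 (SD, n = 2) in untreated cells, 0.89 with ICRF193, 0.68 with bleomycin and 0.46 with camptothecin, against -0.29 in naked DNA and -0.27 after amanitin. Amanitin together with ICRF193 left 0.22 and together with camptothecin 0.38, and recovery reached 0.20. Neither Pol II (-0.06) nor topoisomerase I (-0.08) was enriched in that window, and RNA was detected at 28.0 percent of its probes. On chromosome 1 the window 16992001 to 16996000 had Pol II at -0.29 and topoisomerase I at -0.54. The naked DNA, bleomycin and inhibitor values, with those of both combinations, follow the value table and change sign as labelled.

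Windows with more RNA than others of equal GC content carried slightly more bTMP. Within GC deciles, the upper RNA group exceeded the lower by 0.048 ± 0.015 (SD, n = 2) in untreated cells, in 10 of 10 deciles, and by 0.039 ± 0.023 after recovery. The difference was 0.000 ± 0.032 after amanitin and -0.001 ± 0.004 in naked DNA, but amanitin with ICRF193 had 0.037 ± 0.009 and amanitin with camptothecin 0.037 ± 0.006, in 10 of 10 deciles each, which change sign as labelled. Split by Pol II instead of RNA, untreated cells showed 0.013 ± 0.019. Topoisomerases IIα and IIβ, whose single windows were poorly determined, peaked at the centre of CpG-island-like sites, by 0.129 ± 0.027 and 0.103 ± 0.050 over the flanks.

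The 5 windows still lower after recovery prompted the hypothesis that recovery was incomplete where amanitin had lowered bTMP most. The 50 windows with the largest fall were chosen in 1 replicate and measured in the other, so that no array served for both. Chosen in replicate 1, they lay at -0.189 in recovery minus untreated of replicate 2 (40 of 50 below 0), against -0.0715 to -0.0234 for 10000 random sets with the same GC deciles. Chosen in replicate 2, they lay at -0.112 in replicate 1 (33 of 50), against -0.0426 to 0.00165. Without the 5 windows themselves the values were -0.132 (random -0.0643 to -0.0212) and -0.0498 (-0.0372 to 0.00278). Without the 180 windows within 100 kb of them they were -0.129 (-0.0633 to -0.0219) and -0.0421 (-0.0338 to 0.00756). These values lay closer to the random sets, above all in the second direction, and neighbouring windows are not independent, so the random sets are narrower than chance. Whether recovery may be incomplete beyond the 5 windows therefore stays open.

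Whether equally numbered replicates were pairs was examined through their deviations from the group mean. The deviations correlated across windows with r 0.332 between untreated and amanitin, 0.23 between untreated and recovery and 0.382 between amanitin and recovery. Groups on different slides reached similar values, with 0.415 between naked DNA and camptothecin, 0.413 between bleomycin and camptothecin and 0.333 between bleomycin and naked DNA. The replicate number also matched the labelled dye in every bTMP group, whereas the ChIP groups had the opposite order of dyes. Against these the bTMP groups ranged from -0.391 (amanitin with topoisomerase I) to 0.258 (naked DNA with Pol II, a value that changes sign as labelled), with both signs among the groups. A shared slide does not give the values between slides, and dye and pairing were not separated.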
